A study of Homo sapiens with 12 samples.

How the data were processed

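Human embryonic kidney HEK293 cells, an established line, had been engineered with the Flp-In T-REx system to produce either wild-type DIS3L2 (WT) or its catalytic mutant (mut) from a doxycycline-inducible cassette. Per the labels, the same cassette carries short hairpins embedded in microRNA backbones that silence the endogenous transcript, and the DIS3L2 coding sequence was recoded to escape them. Before RNA isolation the cassette was induced for 3 days with 100 ng/ml doxycycline. Each variant was profiled in 3 total RNA libraries and 3 small RNA libraries. The total RNA libraries were rRNA-depleted, strand-specific TruSeq libraries. The small RNA libraries came from TAP-treated RNA and were selected on gels for inserts of 20 to 200 nt, per the labels, while the series description gives a higher upper limit. The labels call the libraries replicates and nothing in them says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Nor is it stated whether each variant was represented by 1 or several cell lines.

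The submitters' processing notes name CASAVA 1.8.2, STAR 2.4.0, SAMtools 1.2-10, HTSeq 0.6.1, FastQC 0.11.3 and DESeq2 1.8.2 without their roles, and the hg38 build. The version of the gene annotation and the strand setting of the counting are not given in the sources used here. For total RNA the authors deposited raw read counts for 60483 Ensembl genes per library, with separate rows for reads outside genes, reads overlapping several genes and reads with several alignments. For small RNA the authors deposited, per feature, the fragment count, FPM (fragments scaled to library depth, a signal) and FPKM. FPKM equals the FPM signal divided by feature length in kb, as checked in every row of the deposited files. The 15590 small RNA features comprise 10147 Ensembl transcripts, 649 tRNAscan genes and 4794 loci reconstructed from the reads. Annotated features lie within reconstructed loci, so a fragment can count more than once, and the library totals used here are the denominators behind the deposited FPM signal.

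Gene symbols were matched to 56321 of the 60483 Ensembl identifiers, and RefSeq gene types to 39378. Small RNA features carry transcript identifiers only. Their names were taken from RefSeq genes of assembly GRCh38.p14, the same build, where both ends lay within 5 nt, which named 5565 of the 10796 annotated features (28 of them ambiguous). Named features held 96.3% of the fragments of all annotated features. Coordinates are hg38, from RefSeq for total RNA and from the deposited files for small RNA. In total RNA, reads that overlap several genes or have several alignments are not in the gene counts, so overlapping genes and near-identical copies of snRNA, 7SL, histone and snoRNA genes lose reads and values of single copies are uncertain. In small RNA 3 tested features repeat the counts of another and stay in the tests.

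Total counts in genes ranged from 8315986 to 12675042 per total RNA library. Rows that name no gene held 57.8% to 63.2% of all deposited reads and were left out of library sizes and tests. Small RNA library totals ranged from 493314 to 1219718 fragments. No replicate pair agreed within sampling noise, with chi-square per degree of freedom between 1.87 and 3.97 in total RNA and between 11.8 and 129.7 in small RNA, so every library was counted as 1 sample. Confidence intervals are 95% exact Poisson intervals. A fold against a group at 0 uses a floor of 3 counts over the group, and intervals and floors cover counting error only.

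The mut libraries were compared with the WT libraries in each assay apart. Total RNA was tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, R 4.3.3) on 14409 genes, with Benjamini-Hochberg adjustment at 0.05. The design fixed before the data were examined specified limma 3.58.1 on log2(FPKM + 1) for small RNA. It named the edgeR test instead if the files held raw counts. Because the files also hold fragment counts, the same edgeR test was used on the counts of 559 annotated features, and the limma fit became an alternative. The 589 reconstructed loci that passed the filter were tested separately. Standard errors were derived from the log2 fold change and its F statistic. All tests are two-sided.

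Of 39 gene lists fixed beforehand, those with at least 3 tested members were tested with camera at a preset correlation of 0.01, on voom values for total RNA (30 lists) and on log2(FPKM + 1) for small RNA (9 lists). Camera with an estimated correlation and fry were alternatives. Shares of each library in each RNA class were compared with exact permutation tests over 20 assignments, for which the smallest possible p is 0.1. Fold changes of the genes tested in both assays were compared with permutation tests with a smallest possible p of 1e-05.

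The genes named are those a rule fixed beforehand selects. In total RNA these are DIS3L2, the 10 largest rises and 10 largest falls among genes past the test with non-overlapping groups and a mean of at least 1 CPM, the 5 protein-coding genes with the smallest adjusted p in each direction, and up to 4 members of each list by adjusted p. Small RNA followed the same rule with a mean of at least 10 FPKM, and the 1 feature that qualified by size, VTRNA1-2, is also a list member. Members of a list outside the rule are named where their count is small, and 7SK, the analyses by chromosome, gene span and symbol family, and the nuclear tRNA class were chosen after the values were seen.

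The edgeR fit was tested on simulated counts. In total RNA (14183 genes simulated) it recovered 80.3% of 1.5-fold, 90.9% of 2-fold and 100% of 4-fold changes, with 3.8% false calls. In small RNA (549 features simulated) it recovered 25.4%, 69.7% and 100%, with 3% false calls. There 63, 66 and 66 of the features were changed by these folds, a far larger share than the 1 call of 559 in the data. Counts were drawn independently, without the length trends between libraries or the mut library that stood apart. Recovery may therefore be lower and false calls more frequent in the real data. Alternatives covered DESeq2 1.42.0, other scalings, filters and pseudocounts, a 1.5-fold test, limma-voom, protein-coding genes alone, a block on replicate number and leaving out each library. Alternatives chosen after seeing the data included fits with the trend on gene span or feature length removed and a fit without chromosomes 18, 21, 14, 4 and X. In small RNA they also included DESeq2, other scalings of the counts and the fit without a count filter. GC content was not tested because no genome sequence was used here. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.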

Results

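DIS3L2 is a cytoplasmic exoribonuclease that digests RNA from the 3′ end, with a preference for uridylated transcripts, and its loss causes Perlman syndrome. To ask which transcripts depend on its catalytic activity, total RNA and size-selected small RNA were sequenced from HEK293 lines that produced WT DIS3L2 or a catalytic mutant in place of the silenced endogenous protein. There were 3 libraries per variant and assay. Counts in genes were 9009114, 8467957 and 8804231 in the total RNA mut libraries and 9611286, 12675042 and 8315986 in the WT libraries. The small RNA mut libraries held 723919, 1219718 and 503699 fragments and the WT libraries 515938, 493314 and 585737.

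DIS3L2 itself (ENSG00000144535.18, chromosome 2, 231961713 to 232344350) was counted at 1092 ± 51.6 CPM in mut and 784 ± 25.8 CPM in WT total RNA (SD, n = 3), a log2 fold change of 0.48 (SE 0.05, edgeR adjusted p = 1.9e-07). The count may sum transgene and residual endogenous transcripts, and whether reads of the recoded sequence were counted for this gene was not tested. It shows that the gene was counted in cells of both variants and is no test of the silencing.

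In total RNA, 30 of 34 spliceosomal small nuclear RNA (snRNA) genes and 32 of 47 histone genes were higher in the mut cells, with 0 and 2 lower, and 14 of 15 mitochondrial mRNAs and rRNAs were lower. As lists these passed at a preset correlation and not with an estimated correlation (adjusted p = 0.21, 0.22 and 0.33). RNU4ATAC (ENSG00000264229.1, chromosome 2, 121530880 to 121531009), an snRNA of the minor spliceosome, stood at 90.0 ± 7.33 CPM in mut and 5.79 ± 1.35 CPM in WT (log2 fold change 4.0, SE 0.12, adjusted p = 7.5e-20). The U1 variant genes RNVU1-29 and RNVU1-18 rose by 3.98 and 3.97 on the same scale. LCP1, which encodes the actin-bundling protein plastin, rose from 1.81 ± 0.50 to 56.5 ± 1.66 CPM (log2 fold change 4.96, SE 0.13, adjusted p = 2.7e-20). The histone gene H2AC15 rose from 40.3 ± 0.65 to 196 ± 5.07 CPM.

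Across all 14409 genes tested, 1867 were higher and 2049 lower in mut (edgeR, adjusted p under 0.05), of which 188 and 138 differed by more than 2-fold and 515 and 405 by more than 1.5-fold. The 3 mut libraries lay wholly above or below the 3 WT libraries in 40.5% of genes, against 10% by chance. DESeq2 called 1200 higher and 1250 lower, and a test against a 1.5-fold change called 83 and 58. Without the third WT library 1274 genes were lower.

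The largest rises included genes that were silent or nearly so in WT cells. SALL3, a zinc finger transcription factor, had 112 counts in mut and 0 in WT, at least 43.6-fold higher, and the long noncoding RNA KC6 had 57 and 0, at least 22.2-fold higher. AMBN, encoding the enamel protein ameloblastin, had 132 counts against 2, a ratio of 77.1 (95% interval 20.9 to 643), and SFRP2, a secreted Wnt modulator, had 50 against 3, a ratio of 19.5 (6.29 to 97.6). LINC02226 rose by 2.80 and RNU1-2 by 2.76 (log2). Among protein-coding genes NIBAN1 rose by 1.45, and the linker and core histone genes H1-3 and H2AC25 by 0.76 and 0.75. In the other direction the neural adhesion gene LSAMP had 1 count in mut and 127 in WT, a ratio of 109 (19.2 to 4327). MAGEH1 had 1 against 99 and the lymphangiogenic growth factor VEGFC 2 against 63, ratios of 84.7 (14.9 to 3380) and 27 (7.16 to 228). PTCHD1 fell by 4.04, TUSC1 by 3.58, the mitochondrial folate enzyme ALDH1L2 by 3.26, DUXAP9 by 2.53, MIR548F2 by 2.48, NFYAP1 by 2.40 and the sialyltransferase ST8SIA4 by 2.39 on the log2 scale. The falls with the smallest adjusted p among protein-coding genes were the myeloid transcription factor CEBPE (16.8 ± 1.68 against 68.0 ± 4.47 CPM), MAP7D2, ZNF22, TSPO and ZNF320, which fell by 2.01, 1.9, 2.28, 1.73 and 1.75.

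Of 34 spliceosomal snRNA genes tested, 30 rose in mut and 0 fell (31 when adjusted over the list alone), with a median log2 fold change of 1.23. The list passed the test at a preset correlation (camera adjusted p = 3.9e-33), and the estimated correlation gave adjusted p = 0.21. Summed over gene copies, U1 snRNAs stood at 1627 ± 220 CPM in mut and 799 ± 173 CPM in WT, U5 at 316 ± 34.2 and 146 ± 40.6, U6 at 27.9 ± 2.98 and 12.7 ± 2.71, and U6atac at 26.7 ± 5.04 and 15.3 ± 4.53, without overlap between the groups. U4 snRNAs overlapped between the groups, at 1078 ± 257 and 903 ± 260. All 7 tested snRNA pseudogenes, among them RNU5E-4P (1.70), RNU1-27P (2.35), RNU6-33P (1.45) and RNU5A-8P (0.95), rose (camera adjusted p = 3.4e-06; adjusted p = 0.22 with an estimated correlation).

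**Figure D1:**
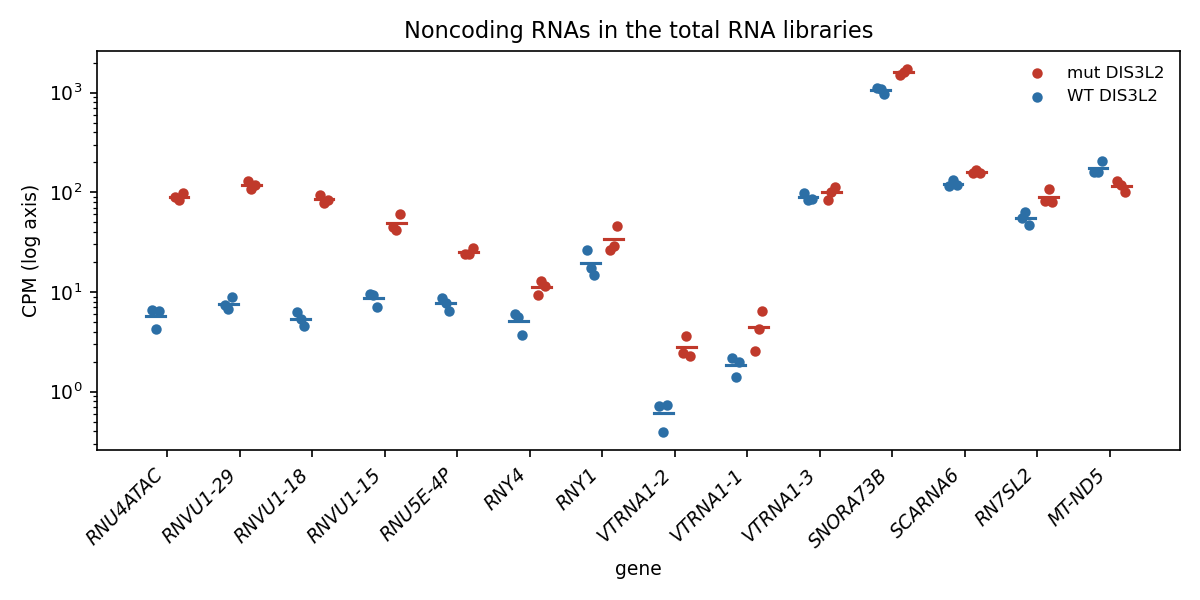
CPM (log axis) of 14 noncoding genes in each total RNA library, mut in red and WT in blue, with a point per library and a line at the mean of 3. RNU4ATAC lies near 90.0 CPM in mut and 5.79 CPM in WT, while the groups overlap for VTRNA1-3 and RNY1.

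Among other short noncoding RNAs, transcripts of RNA polymerase III and small nucleolar RNAs moved the same way in part. The vault RNAs VTRNA1-2 and VTRNA1-1, components of the vault ribonucleoprotein, rose by 2.22 (SE 0.35) and 1.28 (SE 0.29), while VTRNA1-3 was at 99.7 ± 14.8 against 89.1 ± 7.83 CPM (adjusted p = 0.15, and lower by 0.34 with adjusted p = 0.00017 once the trend on gene span, described below, was removed; list adjusted p = 0.024, or adjusted p = 0.36 with an estimated correlation). The list did not pass without mut library 3 or WT library 2 (adjusted p = 0.053 and 0.090). VTRNA1-2 had 22, 31 and 20 counts in mut and 7, 5 and 6 in WT. VTRNA1-1 had 23, 36 and 56 against 21, 18 and 16, and VTRNA1-3 753, 866 and 987 against 948, 1066 and 698. Vault RNAs together made up 0.01065% ± 0.0016 of the mut and 0.0091% ± 0.0009 of the WT libraries, with overlapping groups (exact permutation p = 0.2). Both tested Y RNAs, RNY4 and RNY1, rose by 1.12 and 0.79, but DESeq2 did not call RNY1 (adjusted p = 0.12), whose libraries overlapped between the groups. With the span trend removed the Y RNA median went from 0.95 to 0.50, with 2 genes still higher. The vault RNA median went from 1.28 to 0.81, with 2 higher and 1 lower. RN7SL2, a gene of the signal recognition particle RNA, rose by 0.68, and RN7SL3 was at 108 ± 5.30 against 105 ± 4.47 CPM (−0.17, adjusted p = 0.040, with that trend removed). The transcription regulator 7SK (ENSG00000202198.1), chosen after its values were seen, was at 68831 ± 1590 CPM in mut and 54359 ± 1631 in WT (log2 fold change 0.34, SE 0.04, edgeR adjusted p = 1.6e-07). RMRP, RPPH1, RN7SL1 and VTRNA2-1 are listed at 0 in all 6 libraries, and the sources do not say whether the counting covered them or their reads were dropped for having several alignments. Of the snoRNAs, 8 of 30 box C/D genes and 19 of 52 box H/ACA genes rose and 0 fell (8 and 22 adjusted over the list alone), with the smallest adjusted p for SNORD3B-1 (2.11), SNORD3B-2 (1.10), SNORD17 (0.50) and SNORD94 (0.81) and for SNORA73B (1612 ± 119 against 1063 ± 80.7 CPM), SNORA23 (0.54), SNORA74D (0.77) and SNORA14B (1.09). Both lists passed the preset test (adjusted p = 8.9e-05 and 7.8e-07), with adjusted p = 0.22 and 0.41 at an estimated correlation. Of 12 scaRNAs, 6 rose, SCARNA6, SCARNA5, SCARNA7 and SCARNA13 by 0.26 to 0.39 (list adjusted p = 0.00077; 0.22 estimated). The snoRNA medians of 0.34 and 0.32 turned to −0.18 and −0.07 once the trend of fold change on gene span was removed from each library, a correction chosen after the data were seen, and 5 box C/D and 6 box H/ACA genes were then higher and 0 and 2 lower. The scaRNA median became 0.01, with 0 higher and 1 lower, and 26 of the 34 snRNA genes were past the test as higher, with a median of 0.84. The trend was fitted over all tested genes with a span, these short RNAs included, so it takes up part of their own change. Removing it took the median of protein-coding genes up to 10 kb only from 0.07 to 0.02. Falls of short RNAs after the correction are therefore no separate evidence of a decrease.

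Replication-dependent histone genes, whose messages end in a stem-loop without a poly(A) tail, rose in 32 of 47 cases and fell in 2 (37 and 2 adjusted over the list alone), with a median of 0.33. With the span trend removed 23 were higher and 2 lower, with a median of 0.21. Besides H2AC15, H1-3 and H2AC25, H2BC13 rose by 0.70, and the falls, named after their values were seen, were H2BC10 (−1.03) and H2AC16 (−0.32). The camera adjusted p was 7.9e-19, and 0.22 with an estimated correlation. Among 19 p53 targets 8 rose, including the exonuclease gene AEN (0.62), PHLDA3 (0.70), the cell cycle inhibitor CDKN1A (0.57) and the death receptor TNFRSF10B (0.31), and 2 fell, RRM2B and SESN1 (adjusted p = 0.0075; 0.22 estimated). DNA replication genes rose in 10 of 28 cases, including TYMS (0.44), POLE (0.36), MCM2 (0.34) and MCM5 (0.33), and POLA1 fell (adjusted p = 0.0026; 0.36 estimated). Glycolysis and hypoxia genes rose in 9 of 20 cases, including NDRG1 (0.70), ENO2 (0.55) and PKM (0.43), and EGLN3 and ALDOC fell by 0.70 and 0.79 (adjusted p = 0.012; 0.36 estimated). The snoRNA host genes SNHG12 (0.61), GAS5 (0.41), SNHG15 (0.34) and SNHG29 (0.23) were among 6 of 25 that rose (adjusted p = 0.019; 0.36 estimated). Cytosolic ribosomal protein genes had a median of 0.04, with 16 of 85 higher, among them RPL4 by 0.28 and RPSA by 0.27, and 4 lower, RPS4X, RPL36AL, RPS15 and RPL11 (adjusted p = 0.037; 0.70 estimated). That call was lost without mut library 1, WT library 1 or WT library 3 (adjusted p = 0.34, 0.10 and 0.059), and with the span trend removed 9 genes were higher and 11 lower, with a median of −0.03. The neurofilament gene NEFL, INA and the synaptic vesicle gene SYP rose by 0.51, 0.55 and 0.65 among 5 neuronal markers, and CHGA stood at 1.37 ± 0.54 against 1.73 ± 0.48 CPM (adjusted p of the list 0.013; 0.22 estimated).

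Transcripts encoded by mitochondrial DNA moved the opposite way. Of 15 mitochondrial mRNAs and rRNAs 14 were lower (15 adjusted over the list alone), with a median of −0.46. MT-ND5 fell from 174 ± 25.7 to 116 ± 14.1 CPM, and MT-CO2, MT-CYB and MT-ATP6 fell by 0.56, 0.64 and 0.78. The list adjusted p was 2.7e-09, and 0.33 with an estimated correlation. The 2 tested mitochondrial tRNAs, MT-TW and MT-TP, were at −0.23 and −0.10 (SE 0.36 and 0.23).

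**Figure D2:**
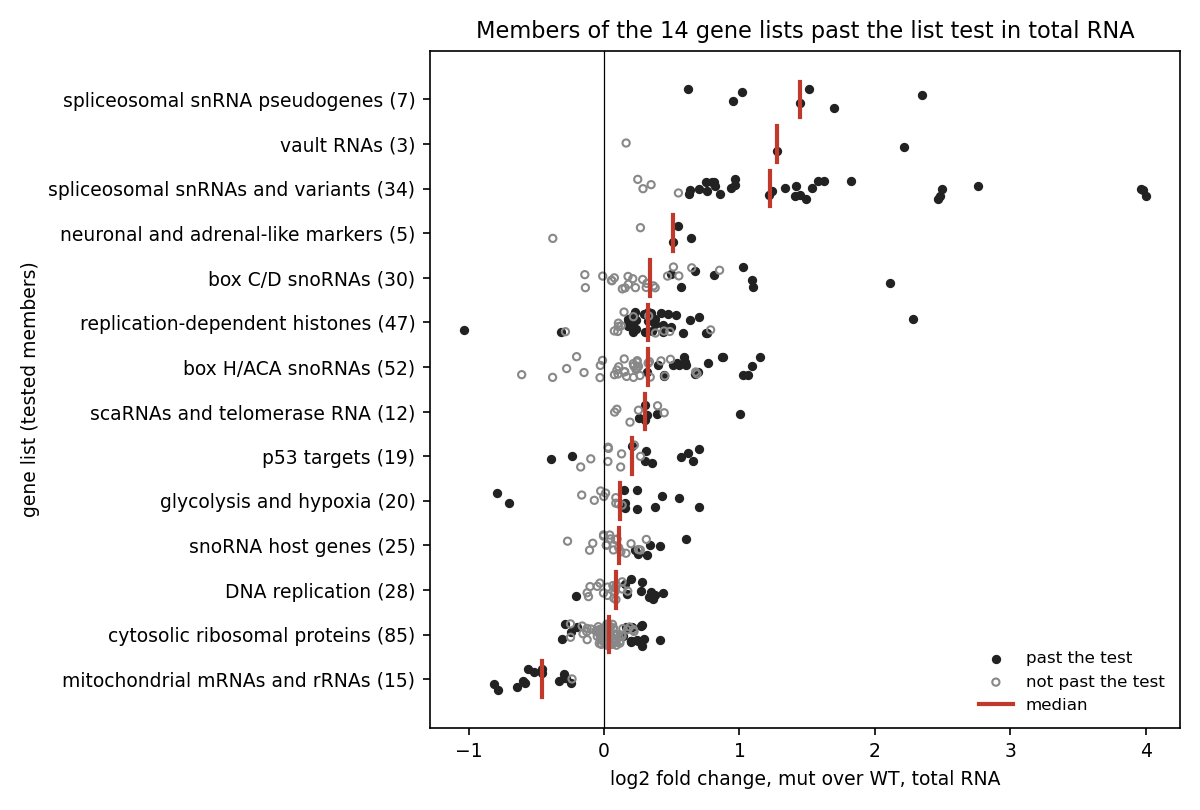
Log2 fold change, mut over WT, of each tested member (points; filled if past the edgeR test) of the 14 gene lists that passed the list test in total RNA, with the median as a red line and the number of tested members in brackets. Medians run from 1.45 for the snRNA pseudogenes to −0.46 for the mitochondrial mRNAs and rRNAs.

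The other lists did not pass (camera adjusted p of 0.066 to 0.87). Among 43 RNA decay and uridylation factors, 8 rose, such as EDC4 (0.47) and SKIC8 (0.39), and 7 fell, including the terminal uridylyltransferase TUT7 (−0.53) and TENT2 (−0.42). Nonsense-mediated decay factors split 4 higher (including UPF1, SMG9 and CASC3) and 3 lower (SMG1, UPF2 and UPF3B) of 16. The stress response list had 5 higher (ATF5 0.70, ATF3 0.67, SESN2, CALR and TRIB3) and 4 lower (SLC7A11 −0.64, STC2, HSP90B1 and SEL1L) of 30. Of 18 signal recognition particle and translocon genes, SRP9 and SEC61A1 rose and SRP54, SSR1 and SRP14 fell. Of 10 protein subunits of RNase P and MRP, RPP25 alone passed, at 4.32 ± 0.34 against 1.13 ± 0.13 CPM, and RPP25L, POP1 and RPP38 lay between −0.11 and 0.19. In the snRNP assembly list 12 of 37 rose, including SNRPE (0.42), TOE1 (0.37), INTS7 (0.34) and SNRPD1 (0.33), and INTS6, INTS2, NCBP2, DDX20 and INTS8 fell. RNA polymerase III genes had 3 higher (GTF3A, GTF3C1 and BRF1) and 4 lower (SSB, POLR3G, SNAPC1 and SNAPC3) of 28. Of 17 Wilms tumour and overgrowth genes, IGF1R (0.35) and IGF2BP1 (0.22) rose and KCNQ1OT1 (−0.63), HMGA2 (−0.30), IGF2BP3 and DICER1 were among 5 that fell. Mitosis genes had CCNB1 higher and CENPE (−0.84), TTK, BUB1B and TOP2A lower among 25, and cholesterol synthesis genes had 4 higher, including LSS, and INSIG1 and STARD4 lower among 17. Of 14 interferon response genes OAS3 fell (−0.34; 0 when adjusted over the list alone, and the call was lost without any 1 of the 6 libraries, adjusted p = 0.052 to 0.16), and IFIH1 and IFIT5 had adjusted p of 0.071 and 0.083.

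Among the short noncoding lists that did not pass, 7SL pseudogenes had RN7SL674P (0.73), RN7SL4P (0.68) and RN7SL5P (0.56) higher and RN7SL751P (−1.60) and RN7SL648P (−0.73) lower of 12. The 7SK pseudogenes RN7SKP203 and RN7SKP80 rose by 0.29 and 0.39 of 5 tested (0.03 and 0.16, no longer past the test, with the span trend removed), and RN7SKP71 and RN7SKP255 had adjusted p of 0.29 and 0.44. The let-7 host transcripts MIRLET7IHG and MIRLET7BHG fell by 0.79 and 0.25 (adjusted p = 0.17 and 0.16 in DESeq2), and MIRLET7A1HG was at −0.12 (SE 0.16). Of 10 microRNA precursors MIR3609 rose (0.38, but −0.14 with the span trend removed), and MIR6797, MIR1282 and MIR621 had adjusted p of 0.059 to 0.14. RNA5SP304, the 1 tested 5S pseudogene, rose by 0.91 (0.45, still past the test, with the span trend removed). No Y RNA pseudogene, U7 or blood cell marker gene passed the count filter. The fibroblast collagens COL3A1 (2.03) and COL1A1 (0.83) rose, both below 3 CPM, with PDGFRA at 1.64 ± 0.25 against 1.10 ± 0.24 CPM (list adjusted p = 0.066), and the epithelial markers EPCAM (0.56) and CDH1 (0.79) rose. DESeq2 did not call COL1A1 or CDH1 (adjusted p = 0.17 and 0.21).

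Several of the named genes lie in chromosome segments whose genes moved together, a comparison made after the data were seen. On chromosome 18, which holds SALL3, KC6, TYMS and SNRPD1, 111 of 181 protein-coding genes were higher and 0 lower, with a median of 0.28. Each chromosome was also divided by gene order into 4 parts of equal gene number. The last part of chromosome 1, from 169463909, had 179 higher and 9 lower of 303 genes, with a median of 0.30, and holds NIBAN1, H2AC25, GAS5, ATF3, PHLDA3, SRP9, SNRPE and INTS7. The last 2 parts of chromosome 15, with RPL4, PKM, RPP25, SKIC8, AEN and IGF1R, had medians of 0.24 and 0.35. The first part of chromosome 14, with CEBPE, EGLN3 and SRP54, had 61 of 104 genes lower and a median of −0.35, and 126 of 414 genes on chromosome X were lower, among them PTCHD1, MAP7D2 and RPS4X. Fold changes also fell with gene span (Spearman −0.23 across 13420 genes, which are not independent replicates), from a median of 0.07 for protein-coding genes up to 10 kb to −0.10 for those over 100 kb. Reads outside genes made up 12.9% ± 0.70 of the mut and 17.9% ± 1.42 of the WT libraries (exact permutation p = 0.1, the smallest possible).

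**Figure D3:**
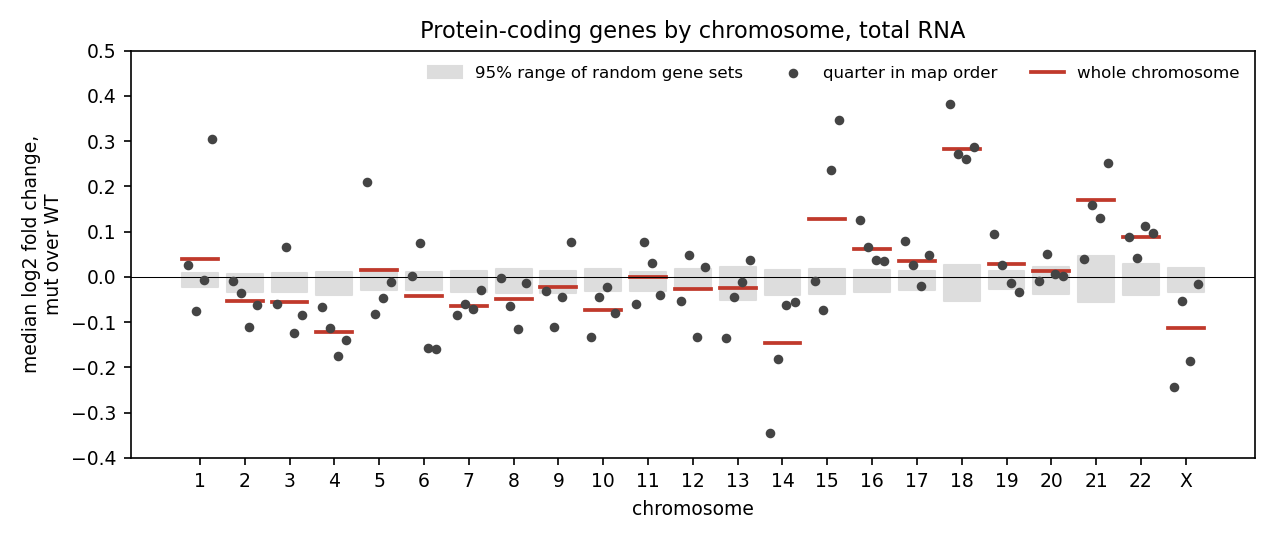
Median log2 fold change of protein-coding genes in total RNA, mut over WT, for each chromosome (red line) and for its 4 parts in map order (points), with the 95% range of random gene sets of the same size in grey. All 4 parts of chromosome 18 lie between 0.26 and 0.38.

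As shares of all gene counts, spliceosomal snRNAs made up 0.317% ± 0.052 of the mut and 0.188% ± 0.048 of the WT libraries, box H/ACA snoRNAs 0.274% ± 0.023 and 0.191% ± 0.022, box C/D snoRNAs 0.087% ± 0.007 and 0.062% ± 0.008, and scaRNAs 0.076% ± 0.002 and 0.062% ± 0.003. Mitochondrial mRNAs and rRNAs made up 10.6% ± 0.65 and 12.9% ± 1.42, most of it the rRNA gene MT-RNR2 (8.82% ± 0.63 and 10.8% ± 1.33). Long noncoding RNAs made up 1.05% ± 0.046 and 1.38% ± 0.033. In each of these classes all 3 mut libraries lay on one side of the WT libraries, with an exact permutation p of 0.1, which is the smallest that 3 against 3 allows (0.16 adjusted over 39 classes).

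In the small RNA libraries VTRNA1-2 (chromosome 5, 140718925 to 140719013) was the 1 feature of 559 past the test. It stood at 87.5 ± 15.2 CPM in mut and 19.4 ± 2.06 CPM in WT (log2 fold change 2.16, SE 0.27, edgeR adjusted p = 0.0072). These levels rest on 65, 99 and 41 fragments in mut and 11, 9 and 12 in WT. VTRNA1-1, at 72.3 ± 24.1 against 31.9 ± 11.7 CPM, and RNY4, at 1600 ± 263 against 852 ± 68.1 CPM, did not pass (adjusted p = 0.31 and 0.11). DESeq2 called RNY4 as well. At an unadjusted p under 0.05 there were 38 features. The call of VTRNA1-2 was lost without mut library 1 (adjusted p = 0.057), WT library 2 (0.096) or WT library 3 (0.13), with log2 fold changes of 2.05 to 2.14. Without mut library 3, 27 features were higher and 3 lower, and the library left out lay below all WT libraries in 13 of the 27 and above all of them in 6. Among the 589 reconstructed loci 1 passed, the locus around VTRNA1-2 (140718903 to 140719110, log2 fold change 2.14, adjusted p = 0.01), and this call was lost without mut library 1, mut library 2, WT library 2 or WT library 3.

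Of the 9 lists tested in small RNA, the vault RNAs were higher (median 1.18; 1 of 3 past the test and 3 adjusted over the list alone; camera adjusted p = 4.4e-07, and 0.045 with an estimated correlation). Spliceosomal snRNAs had a median of 0.35 (0.22 with the trend on feature length removed, chosen after the data were seen), with 0 of 19 members past the test, and passed as a list (adjusted p = 0.0002; 0.58 with an estimated correlation). The members with the smallest p were RNVU1-27 (1.17), RNVU1-15 (1.30), RNU4ATAC (0.71) and RNU5F-1 (0.82). The snRNA pseudogenes RNU5E-4P (1.16), RNU5A-8P (0.73) and RNU5E-6P (0.50) passed as a list in the same direction (camera adjusted p = 0.0076, or 0.58 estimated). Across the settings RNU5A-8P ranged from 0.45 to 1.08 and RNU5E-6P from 0.19 to 0.77. Mitochondrial tRNAs passed in the other direction (camera adjusted p = 0.030, or 0.61 estimated). Their median was −0.20 over 17 members (−0.09 with the trend on feature length removed), of which MT-TL1 is listed 2 times with the same values. MT-TE, MT-TL2 and MT-TL1 were at −0.38, −0.50 and −0.31. Without mut library 1 only the vault RNAs passed, without mut library 2 only the vault RNAs and snRNAs, and the mitochondrial tRNAs were also lost without WT library 2 or 3 (adjusted p = 0.13 and 0.15). Without mut library 3 there were 5 lists higher and 2 lower. The lists of Y RNAs, with RNY1 and RNY3 at 0.13 and −0.05, box C/D snoRNAs (117 tested, median −0.03, or 0.05 with the length trend removed), box H/ACA snoRNAs (89, 0.12, or 0.05), scaRNAs (13, 0.17, or 0.08) and microRNA precursors (3, with MIR16-1, MIR3609 and MIR20A at 0.59, 0.68 and −0.43) did not pass. The listed members with the smallest p were SNORD88B (−0.62), SNORD17 (1.86, but 0.39 without mut library 2), SNORD91B (0.36) and SNORD58A (0.44), SNORA36B (1.11), SNORA2B (0.65), SNORA14B (0.59) and SNORA73A (0.68), and SCARNA16 (0.83), SCARNA15 (0.59), SCARNA4 (0.38) and SCARNA1 (0.64), each with adjusted p of 0.36 to 0.77. Across the settings SCARNA1 ranged from 0.14 to 1.05 and MIR3609 from 0.26 to 1.11. RNU7-1 was at 0.02 (SE 0.17), with either sign across the other settings, and RNA5SP202 at 0.67 (SE 0.33).

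Spliceosomal snRNAs made up 46.0%, 42.8% and 22.3% of the small RNA mut libraries and 32.9%, 28.5% and 32.3% of the WT libraries, a difference within the spread of the mut libraries (exact permutation p = 0.5). Vault RNAs made up 0.025% ± 0.001 of the mut and 0.012% ± 0.002 of the WT libraries, and all 3 mut libraries were higher (exact permutation p = 0.1, or 0.7 adjusted over 28 classes). Box C/D snoRNAs took 27% ± 5.83 and 28.7% ± 1.71, nuclear tRNAs 14.1% ± 3.43 and 17.6% ± 0.76, mitochondrial tRNAs 3.75% ± 0.86 and 4.54% ± 0.52, and box H/ACA snoRNAs 2.98% ± 0.45 and 3.03% ± 0.38 (exact permutation p of 0.3 to 0.9).

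**Figure D4:**
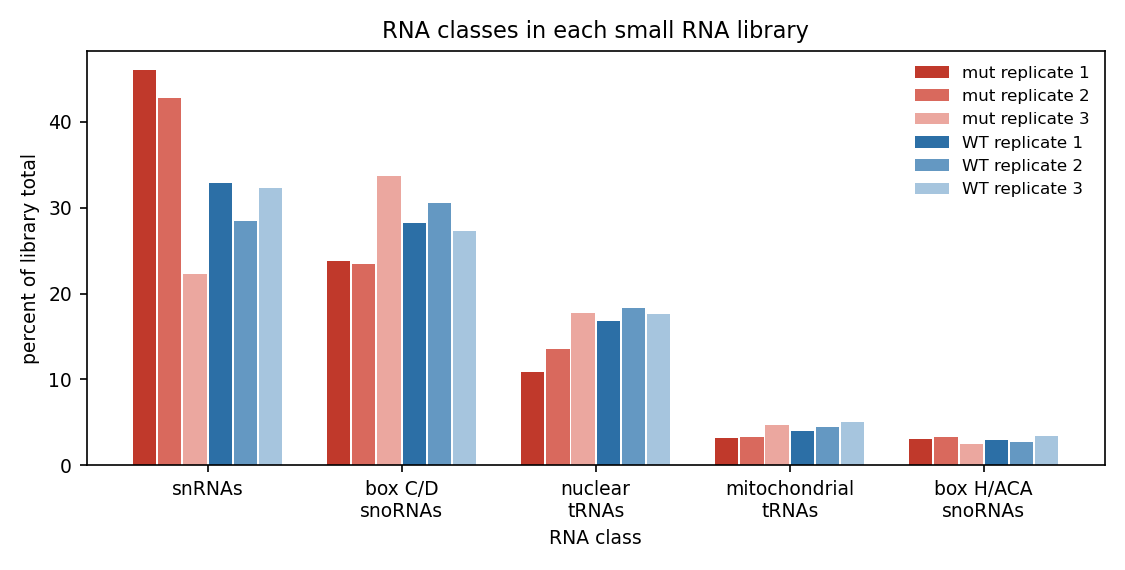
Percent of each small RNA library taken by 5 RNA classes, with a bar per library (mut in red shades, WT in blue shades). Mut library 3, with 22.3% snRNAs and 33.7% box C/D snoRNAs, lies apart from mut libraries 1 and 2, with 46.0% and 42.8% snRNAs.

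Changes in the 2 assays were compared over the 87 genes tested in both, all of them noncoding. The log2 fold changes correlated with Spearman 0.47 and Pearson 0.55 across genes (permutation p = 1e-05 for both, the smallest that the resampling can give), and 67.8% had the same sign, against 53.5% without replicate 1 and 52.9% without replicate 2. Genes are not independent replicates, and the labels do not say whether both assays used the same RNA. Of the 41 genes higher in total RNA, 33 were above 0 in small RNA, against 24 of the other 46 (Fisher's exact p = 0.0069). VTRNA1-2 was the 1 gene higher in both tests, against 0.47 expected from independent lists (Fisher's exact p = 0.47).

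**Figure D5:**
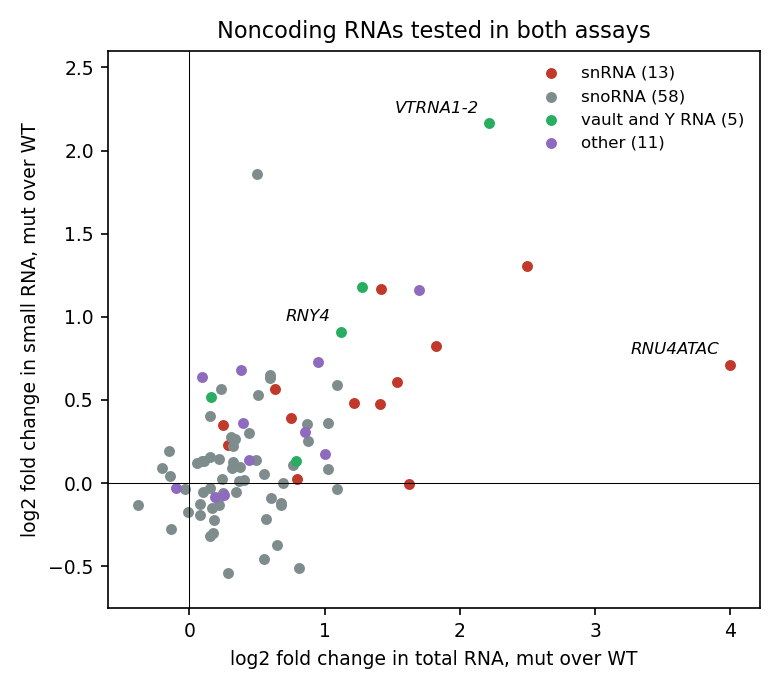
Log2 fold change, mut over WT, in total RNA (x axis) and small RNA (y axis) for the 87 genes tested in both, coloured by RNA type. VTRNA1-2 lies at 2.22 and 2.16 and RNU4ATAC at 4.0 and 0.71.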

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

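The tests of gene span, of carry-over, of near-identical copies, of the snRNAs against their chromosomes, of a wrong label and of other splits were chosen after the result they concern was seen. Reads that overlap several genes, which no comparison used, made up 9.25% ± 0.63 of the mut and 7.68% ± 0.71 of the WT total RNA libraries, a difference between the groups in each library (exact permutation p = 0.1, the smallest that 3 against 3 allows).

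Protein-coding genes of some chromosomes moved as blocks in total RNA, with chromosome 18 higher (median 0.28, 95% range of random sets −0.05 to 0.03) and chromosome 14 lower. With the trend on gene span removed the median of chromosome 18 was 0.33 and that of chromosome 14 −0.12, which argues against span as the cause. A different chromosome content of the mut and WT cells may account for the blocks, as a hypothesis. Each of the 4 parts of chromosome 18 was shifted, the lowest by 0.26. With 111 of its 181 genes higher, 0 lower and 90.1% above 0, that outcome was nearly fixed, so it is no separate evidence for the hypothesis. DIS3L2 variant and any difference between the engineered cells go together in this design, so a direct effect of the variant on these genes stays open and untested.

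Spliceosomal snRNAs rose in total RNA. Carry-over of more short RNA into the mut libraries, equal for all short RNAs, is argued against as the whole cause. The median of 32 snRNAs exceeded that of 90 snoRNAs and scaRNAs of 60 to 250 nt by 0.91 (permutation p = 1e-05, the smallest possible). That permutation treats genes as independent, and 29 of those 90 were higher too. Other short RNAs were outside the comparison, and some rose as much as the snRNAs (median 1.23). Medians were 1.45 for 7 snRNA pseudogenes and 1.28 for 3 vault RNAs, of which VTRNA1-3 was not past the test. Carry-over that differs between RNA classes, or that makes up part of the rise, stays open. Reads moved between counted near-identical copies are argued against, because the share of all snRNA genes was 1.68 times as high in mut, with 0 copies lower (edgeR). Reads with several alignments are not in the gene counts and made up 39.9% ± 2.37 of the mut and 34.5% ± 4.56 of the WT libraries (exact permutation p = 0.2). Reads passing from these into the counted copies could raise the share with no copy lower, so this stays open. Different content of whole chromosomes is argued against at the size seen, since the median of 33 snRNAs on 8 chromosomes lay 1.09 above that of the coding genes of their own chromosome. The 12 of them off chromosome 1 had a median of 1.08, with 9 higher. A local difference in copy number at the snRNA genes themselves was not tested and stays open. In small RNA the groups overlapped for each snRNA family summed over copies. U6 and U6atac were there 0.96 and 0.94 times as high in mut as in WT, against 2.2 and 1.75 times in total RNA. The other families ranged from 1.04 times (U11) to 1.49 times (U4atac, against 15.5 in total RNA). For U1, U2, U4, U5 and U4atac the overlap came from mut library 3 alone. Mut libraries 1 and 2 lay above all WT libraries (U5 at 283900 and 292200 CPM of the library total, against at most 198600). For U6 they lay below all WT libraries, and U6atac, U11 and U12 overlapped without mut library 3 too. The 27 features higher without that library included U1, U4, U5 and U4atac snRNAs, and no snRNA was among the 3 lower. Its snRNA deviation is unexplained, so small RNA does not decide the rise. An effect of the DIS3L2 variant and another difference between the engineered cells stay open, and the rise as a consequence of the variant is a hypothesis.

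Small RNA mut library 3 stood apart from mut libraries 1 and 2. Different size selection may account for this, as a hypothesis, because among 219 snoRNAs and scaRNAs its deviation fell with feature length (Spearman −0.79), although the WT libraries also showed trends, from −0.41 to 0.54, and deviations within a group of 3 mirror each other. Within the snRNAs, where its median deviation was −0.83, and within the tRNAs there was no clear trend (Spearman −0.16, permutation p = 0.51 over 19 features, and −0.097, permutation p = 0.11 over 266), so size selection is not shown for those classes. A WT library under the mut label is argued against, because its vault RNAs, a list that passed without this library too (adjusted p = 0.00013), stood at 234 CPM of the library total (95% interval 194 to 281) against at most 142 in WT, although of the 27 features higher without this library it lay below all WT libraries in 13 and above all of them in 6. No biological explanation was tested.

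Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1) gave as many changed genes in total RNA (3916, and at most 0 in the others), and 1 gave as many gene lists (14, at most 9). In small RNA 2 splits gave as many features (1 in the real split, at most 8 in the others) and 4 gave as many gene lists (4, at most 6). With 10 splits no share under 0.05 is possible. The split with 8 features set mut libraries 1 and 2 and WT library 3 against the rest, the same sides as the signs of the length trend among snoRNAs and scaRNAs. Whether those 8 features follow feature length was not tested.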

How the results depend on the processing

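The gene span, feature length and chromosome alternatives were chosen after seeing the data. So were DESeq2, other scalings of the counts and the fit without a count filter in small RNA. Of the 132 named genes past the test in total RNA, 110 stayed past it with the same direction in each alternative but the 1.5-fold test, in which 94 were lost. DESeq2 lost 14, leaving out some library 13 and removing the span trend 8, and MIR3609 reversed with that trend removed. Scalings moved the median of all genes by under 0.1. DESeq2 lost RNY1, RNU5A-8P, RN7SL674P and COL3A1 (the last with no adjusted p), and the span trend SCARNA5, SCARNA6, SCARNA7, SCARNA13, RN7SKP203, RN7SKP80, RN7SL4P and RN7SL674P. Lost in DESeq2 and without each library named, with the adjusted p there, were OAS3 (any of the 6; 0.052 to 0.16), MIRLET7BHG (any but mut 1; 0.052 to 0.11), MIRLET7IHG (mut 1 or 3, WT 1 or 3; 0.051 to 0.17), COL1A1 (mut 1 or 2, WT 1 or 3; 0.063 to 0.19), CDH1 (mut 2, WT 1 or 3; 0.056 to 0.20), RN7SKP203 (mut 2 or 3, WT 2 or 3; 0.064 to 0.13), RN7SKP80 (mut 2, WT 1 or 2; 0.051 to 0.19), RN7SL4P (mut 1, WT 1 or 3; 0.051 to 0.080), POLR3G (mut 3, WT 1; 0.057 and 0.073) and UPF2 (mut 1, WT 3; 0.13 and 0.14). BUB1B (WT 3; 0.054), SMG9 (WT 1; 0.077) and UPF1 (WT 1 or 3; 0.059 and 0.070) were lost only without a library. Where no cause is given below, the cause was not tested.

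Total RNA calls, 1867 higher and 2049 lower, became 1200 and 1250 with DESeq2 and 83 and 58 against a 1.5-fold change, which asks for larger changes. RLE gave 1924 and 1977, library size 1836 and 2077, limma-voom 1867 and 2023, no filter 1677 and 2113, a mean of 1 CPM 2026 and 1888, protein-coding genes alone 1827 and 1707, the span trend removed 1968 and 1951, and 5 shifted chromosomes left out 1677 and 1543. Leaving out a library gave 1327 to 1832 higher and 1274 to 2109 lower. Small RNA calls, 1 and 0, became 2 and 0 with DESeq2, 12 and 2 without a filter on low counts, and 0 to 27 higher and 0 to 3 lower without a library. Reconstructed loci, 1 and 0, became 2 with DESeq2, 2 with RLE, 23 and 4 without a filter, and 0 to 36 higher and 0 to 6 lower without a library.

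Deviations of same-numbered libraries from their group means correlated at −0.089, −0.073 and 0.032 in total RNA and 0.2, −0.142 and −0.362 in small RNA. They gave no sign of pairing by number, but so few values, which mirror each other within a group, cannot decide whether the numbers pair the libraries. A replicate block gave 1675 and 1845 calls in total RNA, 1 and 0 in small RNA with edgeR, 0 with limma (56 at an unadjusted p under 0.05) and 0 among reconstructed loci (edgeR, 36 at an unadjusted p under 0.05). With the block 13 total RNA lists and 4 small RNA lists were called, of 14 and 4 without it. Among named genes the block ended the calls of OAS3 and MIRLET7BHG, as did the fit without a filter.

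List calls in total RNA, 13 higher and 1 lower, were 0 and 0 with an estimated correlation and 18 and 1 with fry. In small RNA, 3 and 1 became 1 and 0 with an estimated correlation, 1 and 0 with fry, and 1 to 5 higher and 0 to 2 lower without a library. Between genes of the 2 assays, Spearman was 0.371 to 0.429 and the same-sign share 52.9% to 65.1% without a replicate number. With the length trend removed, small RNA list medians went from 0.35 to 0.22 for snRNAs, −0.20 to −0.09 for mitochondrial tRNAs, 0.12 to 0.05 for box H/ACA snoRNAs, 0.17 to 0.08 for scaRNAs and −0.03 to 0.05 for box C/D snoRNAs. Protein-coding genes alone gave no value, since none was tested in both.

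These values changed sign, and none but MIR3609 had passed the test. With the span trend removed, RN7SL3 was −0.17, RN7SKP255 −0.050, VTRNA1-3 −0.34, MIR3609 −0.14 and MIR621 −0.19, and VTRNA1-3 and RN7SL3 then passed the test as lower (adjusted p = 0.00017 and 0.040). The fitted trend takes in these short RNAs themselves, so these falls are no separate evidence of a decrease. Without a library, MIRLET7A1HG was −0.30 to 0.017, MT-TW −0.51 to 0.020, MT-TP −0.25 to 0.03 and RNY3 −0.21 to 0.11, and with the length trend removed RNY3 was 0.0094. RNU7-1 was −0.059 with library totals, −0.059 with limma (also without a filter, above 10 FPKM and with the replicate block), −0.059 and −0.059 with pseudocounts of 0.1 and 10, and −0.058 to 0.13 without a library. Differences in small RNA shares without a library, in percentage points, were −5.05 to 0.083 for box C/D snoRNAs, −0.23 to 0.20 for box H/ACA snoRNAs (0.071 without the most abundant gene) and −0.0093 to 0.015 for scaRNAs. In small RNA 25.4% of simulated 1.5-fold changes were recovered, with a biological coefficient of variation of 21% against 5.22% in total RNA, and depth was not varied. GC content could not be tested without a genome.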

Other observations

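Gene families were searched after the data were seen, by the letters that open gene symbols, over 183 families. Zinc finger genes whose symbols begin with ZNF were lower in mut, 186 lower and 17 higher of 481, with a median of −0.23 (camera adjusted p = 2.8e-10; adjusted p = 0.93 with an estimated correlation). Of 17 ZFP genes 6 were lower and 0 higher by edgeR (adjusted p = 0.039; 0.93 estimated), and of 38 CEP genes, many of which encode centrosomal proteins, 17 were lower and 2 higher, with a median of −0.22 (adjusted p = 0.0037; 0.93 estimated). Removing the span trend left medians of −0.23, −0.26 and −0.16. No other explanation was tested.

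Bitter taste receptor genes of the TAS2R family were lower in 12 of 13 cases, with a median of −1.21 (adjusted p = 1.9e-07; 0.93 estimated). All 12 lie on chromosome 12 between 10907926 and 11134644, within the limits of PRH1 (10880965 to 11171611), which fell by 1.34, and next to PRR4, which fell by 0.95. TAS2R14 was at 3.21 ± 0.39 against 6.50 ± 0.55 CPM, TAS2R30 at 3.98 ± 0.34 against 9.39 ± 1.31 CPM and the pseudogene TAS2R64P at 2.68 ± 0.26 against 6.90 ± 0.21 CPM. Whether the 12 changed independently was not tested.

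Other searches made after the data were seen covered the medians of 23 chromosomes, trends on gene span and feature length, and the regions flanking genes, which were dropped. Whether a few strongly changed genes made up the shift of chromosome 18 was asked of genes not past the test (median 0.13, random upper bound 0.03) and then of the share above 0 (90.1%). Both were dropped as tests, since 111 of the 181 genes had already been seen to be higher. A test of the snRNA rise with the span trend removed (26 of 34 past the test as higher) was replaced by the one on chromosome content. The test of a wrong label on vault RNA levels was replaced by one on the 27 features higher without that library, and then restored with the condition that the vault list pass without it. Those tests were first written after the calculations had run but before the output was viewed, and the replacements after it was viewed.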
